A study of Mus musculus with 33 samples.

How the data were processed

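The series holds 33 RNA sequencing libraries of proximal small intestine from C57Bl/6J mice, 8 of the WT group, 19 of the Apc group and 6 of the ApcKras group. Per the labels, total RNA of 1 cm of tissue was made into TruSeq RNA v2 libraries and sequenced on a NextSeq in pairs of 36-base reads. The deposited table gives raw counts per Ensembl gene, with 1 column per library and no normalization. Per the submitters' processing notes, FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0 and featureCounts 1.6.4 were used with GRCm38. The annotation release, the strand setting and any filter are not given in the sources used here. The library kit is not stranded, so counts of genes that overlap on opposite strands cannot be told apart. All 33 columns were used.

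The 55421 Ensembl identifiers were matched to symbols (55154 matched) and to GENCODE M21 on GRCm38 for coordinates (55240 matched). In all, 15885 genes had no counts in any library. Library totals were 10483112 to 34964866 counts, with group medians of 18467982 in WT, 18621953 in Apc and 15277896 in ApcKras. No pair of libraries was a duplicate. Replicate numbers do not pair the samples: over 20 pairs of equally numbered samples the correlation of deviations from the group means had a median of -0.058. In 3 of the 20 pairs the first sample had its namesake as best partner in the other group.

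Genes were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10 in a library of median size in at least as many libraries as the smallest group (6) and a minimum of 15 counts in total, which left 18539 genes. Counts were scaled by TMM factors, and CPM are TMM-scaled. The 3 groups were fitted in a single quasi-likelihood model without further terms (estimateDisp, glmQLFit and glmQLFTest), and each of the 3 pairs of groups was compared with Benjamini-Hochberg adjustment over the genes tested, at adjusted p under 0.05. A fold of at least 2 was a further count, not a condition. Log2 fold changes are printed ± SE and CPM ± SD. Computation used R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

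The comparisons, the tests, 35 gene lists of signalling targets, cell types and metabolic functions, the rule for named genes and the alternatives were chosen before the data were examined. List names do not cover every member. The amino acid list also holds stress-response genes such as Trib3 and Chac1. The lipid absorption list holds the mitochondrial importer gene Cpt1a, and the glycolysis list the carbonic anhydrase gene Car9. For each list, members higher, lower and not called were counted, adjusted over all genes and over the list alone. Lists were tested by camera of limma with an inter-gene correlation of 0.01, and beside it with an estimated correlation and by fry, each adjusted over the 35 lists. The rule for named genes takes Apc and Kras, then per comparison the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between samples, and for each described list the 3 members with the smallest p. Symbols starting with Gm and a digit or ending in Rik, and genes without a symbol, were passed over. The rule gave 121 genes with 145 results.

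A further 4 alternatives were chosen after seeing the data. The first was an exact two-sided permutation test of the mean log2 CPM of each list (adjusted over the 35 lists; the smallest p it can give is 4.50e-07, 0.000333 and 5.65e-06 in the order Apc against WT, ApcKras against WT and ApcKras against Apc). The others were the libraries with fewer than 21000000 counts (6 WT, 10 Apc and 6 ApcKras), the libraries with Y-linked expression (5 WT, 15 Apc and 4 ApcKras), and list members counted without ApcKras replicate 1. Those chosen in advance were DESeq2 with its own size factors and independent filtering, limma voom with sample quality weights, and RLE and upper-quartile factors in edgeR. They also included no filter beyond 1 count, a filter of 1 CPM in 6 samples, the replicate number as a replicate block, the expression of Y-linked genes, a smooth muscle score or 1 surrogate variable as a covariate, only the compared groups, 6 samples drawn per group in 20 draws, each sample left out in turn, and the estimated correlation for lists. In the replicate block, Apc replicates 9 to 19 have no equally numbered sample in another group, so they do not bear on its fold changes. Overlaps of calls were set against independent lists, 20 simulations of unchanged groups with shared WT samples, and WT samples divided in 2 sets of 4. Each count of calls was set against 100 random regroupings of the same libraries, the real one included.

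The tests were tried on simulated counts drawn from the means and library sizes of the real samples, over 18262 genes. In the simulation of Apc against WT with 200 changed genes, edgeR recovered 55.2% of the changes of 1.5-fold, 83.6% of 2-fold and 95.5% of 4-fold, and 4.88% of its calls were false. In that of ApcKras against WT it recovered 46.3%, 80.6% and 98.5% of 200 changed genes, with 3.85% false. In that of ApcKras against Apc it recovered 54.5%, 82.1% and 95.5% of 400 changed genes, with 5.50% false. Among 35 simulated lists with 1 changed, camera called that list and 0 others. The genes were drawn independently of each other, so this cannot show false calls that come from correlation between list members. Simulated counts carried counting error and, on top of it, the spread between samples fitted to each gene. The labels give no sex and no batch, so neither was a group of the design.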

Results

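RNA was sequenced from 33 samples of mouse small intestine, each 1 cm of the proximal part taken as whole tissue, so epithelium, stroma, muscle and immune cells were measured together. All samples carried VilCreER, a tamoxifen-inducible Cre recombinase made in intestinal epithelial cells. The WT group (8 samples, day 4 after induction) carried the Cre alone. The Apc group (19 samples, day 4) also carried Apc fl/fl, so that induction removes Apc, a brake on Wnt signalling, from the epithelium. The ApcKras group (6 samples, day 3) carried Apc fl/fl and KRasG12D/+, an activated form of the GTPase that drives the ERK pathway. The libraries held 14959852 to 28254448 counts in WT, 10483112 to 34964866 in Apc and 13683194 to 18367645 in ApcKras, and mitochondrial genes took 3.01% to 5.61% of the counts of a library. Of 55421 genes, 18539 had enough counts to be tested. The labels do not say whether the samples of a group came from separate mice, so the p-values measure the spread between these samples, which may be in part technical.

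On principal components of log2 CPM (counts relative to library size, scaled by TMM factors), component 1 (31.0% of the variance) parted the WT libraries from the other groups, and 4 of the 6 ApcKras libraries lay above all Apc libraries on component 2 (13.1%). A set of 9 libraries, WT replicates 5, 6 and 8, Apc replicates 10, 11, 12 and 19 and ApcKras replicates 3 and 4, lacked Y-linked expression and had 398.6 to 786 CPM of Xist, against at most 1.70 in the others. Their scores lay apart from all others of their group in 14 of 34 gene lists in WT (1.21 by chance), 0 in Apc (0.0175) and 18 in ApcKras (4.53), the sex-linked list not counted. The Y-expressing libraries (5 WT, 15 Apc and 4 ApcKras) were therefore also tested alone, a choice made after seeing the data. On component 4 (5.74%) Apc replicates 1 to 11 lay at 7.25 to 45.2 and replicates 12 to 19 at -24.9 to -7.87. All 6 ApcKras libraries lay at -29.9 to -4.75, and the WT libraries at -14.6 to 17.4. The labels do not tell whether a batch divides the Apc libraries, and its weight in ApcKras against Apc was not tested.

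**Figure D1:**
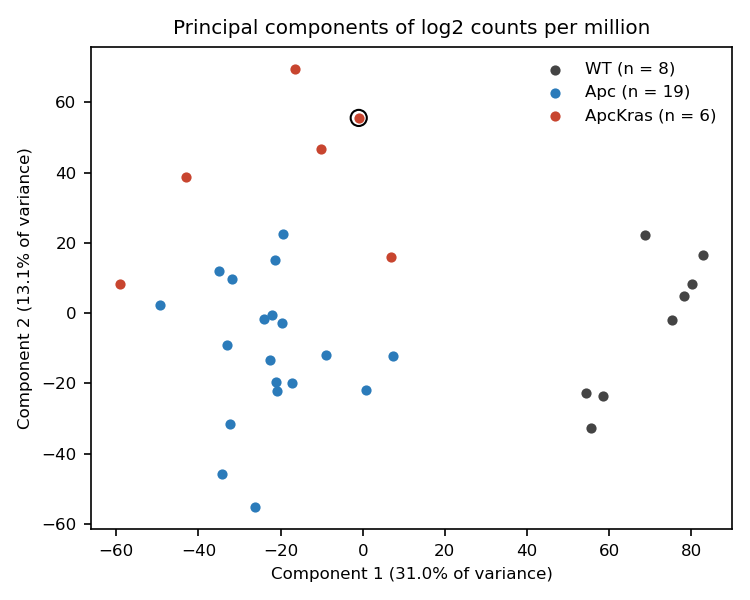
Each point is 1 library, placed by its scores on principal components 1 and 2 (31.0% and 13.1% of the variance), in grey for WT (n = 8), blue for Apc (n = 19) and red for ApcKras (n = 6). The WT libraries lie to the right of all others, and the circle marks ApcKras replicate 1.

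The targeted genes themselves were still transcribed in all 33 samples. Apc (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552 on GRCm38) had 77.8 to 111 CPM in the WT samples, 73.1 to 143 in Apc and 64.8 to 175 in ApcKras. Its mean ± SD was 95.4 ± 9.98 CPM in WT (n = 8), 118 ± 16.7 in Apc (n = 19) and 124 ± 37.9 in ApcKras (n = 6). By edgeR quasi-likelihood, with Benjamini-Hochberg adjustment, it was higher in Apc than in WT (log2 fold change 0.30 ± 0.11, SE, adjusted p = 0.0177) and in ApcKras than in WT (0.37 ± 0.14, adjusted p = 0.0238). Between ApcKras and Apc it did not pass (0.070 ± 0.12, edgeR adjusted p = 0.704). Single libraries decide whether these small rises pass by edgeR. Without WT replicate 6 the log2 fold changes were 0.25 in Apc (adjusted p = 0.0573) and 0.31 in ApcKras (0.0663), and in ApcKras 0.29 without replicate 3 (0.103) and 0.23 without replicate 4 (0.174). Neither passed in the Y-expressing libraries alone (log2 fold changes 0.25 and 0.061, edgeR adjusted p = 0.102 and 0.802). Over all 47 alternatives the adjusted p ran from 0.00172 to 0.180 for Apc and from 0.000726 to 0.802 for ApcKras. Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239) had 92.3 to 108 CPM in WT, 97.3 to 133 in Apc and 115 to 142 in ApcKras. It was higher than in WT in both groups (log2 fold change 0.23 ± 0.053, edgeR adjusted p = 0.000471, in Apc and 0.38 ± 0.067, adjusted p = 2.37e-05, in ApcKras), and between ApcKras and Apc it did not pass (0.15 ± 0.058, edgeR adjusted p = 0.0550). The rise in Apc was lost with a replicate block (0.12, edgeR adjusted p = 0.10002, in a range from 8.73e-05 over 47 alternatives), to which Apc replicates 9 to 19 do not contribute. Without ApcKras replicate 1 or 6 the last difference passed, at adjusted p = 0.0352 and 0.0250 by edgeR, in a range of 0.0108 to 0.404 over its 47 alternatives. A count over a whole gene shows neither the removal of a floxed exon nor a point mutation, and the unrecombined cells of the tissue transcribe both genes too.

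**Figure D2:**
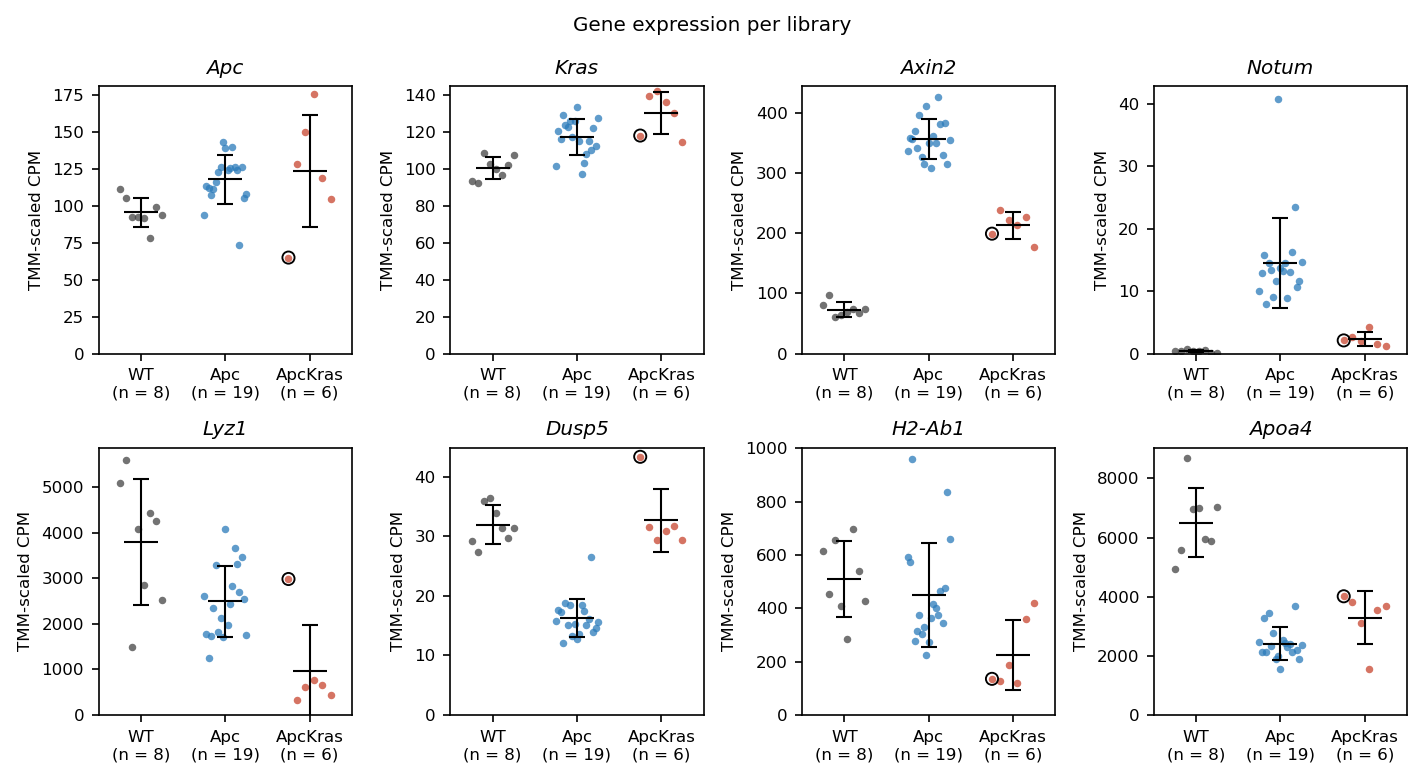
Expression of 8 genes in TMM-scaled CPM on linear axes from 0, with 1 point per library, bars at the mean ± SD, and a circle around ApcKras replicate 1. Axin2 and Notum are highest in Apc, Dusp5 is lowest in Apc, and Lyz1 is low in 5 of the 6 ApcKras libraries.

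The comparison of Apc with WT, both at day 4, asks what loss of Apc alone does to the tissue. Most Wnt targets and stem cell markers rose (20 of 24 and 16 of 17). All 35 cell cycle and all 30 ribosome biogenesis genes rose, at adjusted p = 0.194 and 0.229 with an estimated correlation. Most members of the brush border, lipid absorption, xenobiotic, goblet, enteroendocrine, tuft and T cell lists fell, at adjusted p = 0.194 to 0.370 with an estimated correlation. Of 18539 genes, 5806 were higher and 5795 lower in Apc (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 871 and 1242 of them by at least 2-fold. Of the 8291 called genes with a mean of at least 5 CPM in the higher group and a symbol not passed over by the rule for named genes, 1185 higher and 747 lower genes had no overlap between the samples of the groups.

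Of 35 gene lists fixed in advance, camera at its preset correlation of 0.01 called 17 in this comparison (5 up, 12 down), of which 2 held with an estimated correlation. Since random regroupings of the samples gave as many camera calls, an exact two-sided permutation test of the mean log2 CPM of each list, chosen after seeing this, is given beside camera. It called 27 lists (9 up, 18 down), among them all 17.

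Of the 24 Wnt target genes, 20 rose, 3 fell and 1 did not pass, with 20 and 3 adjusted over the list alone. The Wnt target list had a median log2 fold change of 1.84, camera adjusted p = 1.49e-21, adjusted p = 0.000815 with an estimated correlation, and permutation adjusted p = 1.43e-06. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), the feedback inhibitor that reads out the pathway, rose from 73.0 ± 11.8 to 356 ± 32.5 CPM (mean ± SD, n = 8 and 19; log2 fold change 2.29 ± 0.079, edgeR adjusted p = 5.20e-21). The ubiquitin ligase Rnf43, which clears Wnt receptors, rose by 2.18 ± 0.10 and the stem cell transcription factor Ascl2 by 2.36 ± 0.14 on the log2 scale. Among 17 measured stem cell markers 16 rose, 0 fell and 1 did not pass, with 16 and 0 adjusted over the list alone. The stem cell list had a median log2 fold change of 1.25, camera adjusted p = 4.34e-18, adjusted p = 0.00473 with an estimated correlation, and permutation adjusted p = 1.43e-06. Cdca7, a chromatin factor of dividing cells, rose by 1.88 ± 0.084 and Igfbp4, a secreted binder of insulin-like growth factors, by 2.18 ± 0.14.

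All 35 cell cycle genes rose (35 also adjusted over the list alone; median log2 fold change 0.79; camera adjusted p = 8.14e-17, adjusted p = 0.194 with an estimated correlation, and permutation adjusted p = 1.43e-06). Their transcription factor E2f1 rose from 10.3 ± 2.23 to 24.7 ± 3.26 CPM, and Uhrf1, which keeps DNA methylation through replication, and Tyms, which makes thymidylate, rose by 1.20 ± 0.10 and 0.91 ± 0.078 on the log2 scale. All 30 ribosome biogenesis genes rose (30 over the list alone; median 0.97; camera adjusted p = 3.68e-16, adjusted p = 0.229 with an estimated correlation, and permutation adjusted p = 2.43e-06). In WT the libraries without Y-linked expression had ribosome biogenesis scores of 5.83 to 5.995 and the other 5 of 5.06 to 5.22, and cell cycle scores of 5.33 to 5.55 against 4.90 to 5.18. All genes of both lists rose in the Y-expressing libraries alone too, with medians of 1.31 and 0.99. They include the rRNA methyltransferase Fbl (1.03 ± 0.10), its partner Nop56 (1.18 ± 0.12) and the RNA polymerase I subunit Polr1b (1.01 ± 0.10).

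The absorptive programme went the other way. Of 30 brush border enterocyte genes 0 rose, 26 fell and 4 did not pass, with 0 and 26 adjusted over the list alone. The brush border list had a median log2 fold change of -0.87, camera adjusted p = 3.48e-07, adjusted p = 0.370 with an estimated correlation, and permutation adjusted p = 1.43e-06. The fructose-bisphosphate aldolase Aldob fell from 3569.6 ± 539 to 1338 ± 288 CPM, the disaccharidase Sis from 3869 ± 914 to 1234 ± 476 and the glucose carrier Slc5a1 from 2817 ± 759 to 1263 ± 289.8 (mean ± SD, n = 8 and 19). Of 25 lipid absorption genes 1 rose, 22 fell and 2 did not pass, with 1 and 22 adjusted over the list alone. The lipid absorption list had a median log2 fold change of -1.03, camera adjusted p = 1.20e-08, adjusted p = 0.194 with an estimated correlation, and permutation adjusted p = 1.43e-06. Its members had log2 fold changes of -1.34 ± 0.11 for Mttp, which loads lipoproteins, -1.43 ± 0.13 for the apolipoprotein Apoa4 and -1.65 ± 0.18 for the fatty acid carrier Slc27a4. Of 30 xenobiotic metabolism genes 0 rose, 25 fell and 5 did not pass, with 0 and 26 adjusted over the list alone. The xenobiotic list had a median log2 fold change of -1.29, camera adjusted p = 3.90e-11, adjusted p = 0.229 with an estimated correlation, and permutation adjusted p = 1.43e-06. The glutathione transferases Gsta4 and Gstm3 had log2 fold changes of -2.21 ± 0.20 and -3.01 ± 0.29 and the cytochrome Cyp2c65 of -1.86 ± 0.20.

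Goblet cell, enteroendocrine and tuft cell markers were lower too. Of 19 goblet cell markers 2 rose, 14 fell and 3 did not pass, with 2 and 14 adjusted over the list alone. The goblet cell list had a median log2 fold change of -0.98, camera adjusted p = 1.85e-06, adjusted p = 0.194 with an estimated correlation, and permutation adjusted p = 1.43e-06. The mucus protein gene Clca1 was at 1218 ± 170.2 CPM in WT and 326 ± 77.9 in Apc. The vesicle gene Sytl2 changed by -1.10 ± 0.089 and Bcas1 by -1.84 ± 0.16. Of 23 enteroendocrine markers 1 rose, 19 fell and 3 did not pass, with 1 and 19 adjusted over the list alone. The enteroendocrine list had a median log2 fold change of -0.97, camera adjusted p = 1.15e-06, adjusted p = 0.194 with an estimated correlation, and permutation adjusted p = 1.43e-06. The hormone genes Gcg and Gip and the granule protein gene Chgb changed by -2.01 ± 0.18, -1.61 ± 0.16 and -0.87 ± 0.090. Of 16 tuft cell markers 1 rose, 15 fell and 0 did not pass, with 1 and 15 adjusted over the list alone. The tuft cell list had a median log2 fold change of -1.12, camera adjusted p = 0.000223, adjusted p = 0.194 with an estimated correlation, and permutation adjusted p = 1.43e-06. The kinase Hck (-1.14 ± 0.12) and the phospholipase Plcb2 (-1.10 ± 0.14) fell, while Cd24a, also made by other crypt cells, rose (1.17 ± 0.096). Of 20 T cell markers 0 rose, 19 fell and 1 did not pass, with 0 and 20 adjusted over the list alone. The T cell list had a median log2 fold change of -1.15, camera adjusted p = 9.59e-07, adjusted p = 0.370 with an estimated correlation, and permutation adjusted p = 1.43e-06. Cd4 changed by -1.14 ± 0.16, the gamma-delta receptor gene Trdc by -1.10 ± 0.16 and the receptor subunit Cd3e by -1.22 ± 0.18.

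The largest rise with no overlap between samples was in Msx1 (ENSMUSG00000048450, chromosome 5, 37820485 to 37824583), a homeobox gene of the BMP pathway, from 0.525 ± 0.191 to 38.2 ± 12.1 CPM (log2 fold change 6.15 ± 0.33, edgeR adjusted p = 4.48e-16). It was followed by the vitamin C synthesis gene Gulo (5.95 ± 0.52), the transcription cofactor Cited1 (5.79 ± 0.35), the Wnt-inactivating enzyme Notum (ENSMUSG00000042988, chromosome 11, 120653788 to 120661175; 5.30 ± 0.35), the alkaline phosphatase Akp3 (4.71 ± 0.97) and the iron reductase Cybrd1 (4.40 ± 0.55). The largest falls were in Ugt2b5 (-4.13 ± 0.43), Dnase1 (-3.41 ± 0.41), Ugt1a1 (-3.31 ± 0.36), Cyp2b10 (-3.28 ± 0.38), the phosphate carrier Slc34a2 (-3.27 ± 0.48) and the alcohol dehydrogenase Adh4 (-3.23 ± 0.27). Ugt1a1 shares exons with its neighbours, and reads of such genes are divided with uncertainty.

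Among the lists of stroma and of other immune cells, 16 of 18 fibroblast, 12 of 16 endothelial, 9 of 18 smooth muscle, 14 of 19 enteric neuron and glia and 16 of 19 myeloid genes fell, and 0, 1, 0, 0 and 1 rose. Camera called these 5 lists, with adjusted p from 0.355 to 0.627 with an estimated correlation. The smooth muscle call was lost in the Y-expressing libraries (camera adjusted p = 0.0587, in a range from 0.000554 over 38 alternatives). Those libraries gave 12 fibroblast, 13 endothelial, 5 smooth muscle, 8 enteric neuron and glia and 12 myeloid genes lower. Of 28 ERK output genes 15 rose, 4 fell and 9 did not pass, with 15 and 5 adjusted over the list alone. The ERK output list had a median log2 fold change of 0.43, camera adjusted p = 0.0782, adjusted p = 0.669 with an estimated correlation, and permutation adjusted p = 0.000799, and in the Y-expressing libraries camera adjusted p = 0.000587. Amino acid transport and one-carbon genes (14 of 23 higher, 5 lower, camera adjusted p = 0.00701) rose, at adjusted p = 0.492 with an estimated correlation. The BMP, Notch and glycolysis lists had negative medians (-0.081, -0.10 and -0.093) but positive means (0.16, 0.053 and 0.026) and were not called by camera (adjusted p = 0.809, 0.843 and 0.809). The permutation test follows the mean and called the BMP list higher (adjusted p = 0.0474).

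The comparison of ApcKras with WT asks what the combined change does, at day 3 in ApcKras against day 4 in WT. Most members of the cell cycle, ribosome biogenesis, glycolysis and amino acid transport and one-carbon lists rose, at adjusted p = 0.119 to 0.151 with an estimated correlation. Of 19 Paneth cell, 31 interferon, 10 class II and 20 T cell genes 15, 29, 10 and 19 fell, at adjusted p = 0.375, 0.348, 0.443 and 0.217 with an estimated correlation. Genotype and day cannot be separated here. Of 18539 genes, 5326 were higher and 4574 lower (870 and 2134 by at least 2-fold; edgeR). Of the called genes 53.8% were higher, but 40.5% with upper-quartile factors, which moved the median log2 fold change of all genes to -0.11. Among 6837 called genes with at least 5 CPM and a symbol not passed over, 1791 higher and 998 lower genes had no overlap between the groups. Camera called 23 lists (7 up, 16 down), of which 0 held with an estimated correlation, and the exact permutation test called 28 (9 up, 19 down).

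The Wnt targets rose less than in Apc alone. Of 24, 17 rose, 3 fell and 4 did not pass, with 17 and 3 adjusted over the list alone. The Wnt target list had a median log2 fold change of 1.17, camera adjusted p = 1.05e-08, adjusted p = 0.119 with an estimated correlation, and permutation adjusted p = 0.00117. Axin2 was at 213 ± 21.9 CPM (mean ± SD, n = 6; log2 fold change 1.54 ± 0.089, edgeR adjusted p = 2.44e-14). The log2 fold changes of Rnf43 and the crypt receptor Ephb2 were 1.56 ± 0.12 and 1.61 ± 0.14. Of 17 stem cell markers 12 rose, 0 fell and 5 did not pass, with 13 and 0 adjusted over the list alone. The stem cell list had a median log2 fold change of 0.96, camera adjusted p = 1.44e-08, adjusted p = 0.119 with an estimated correlation, and permutation adjusted p = 0.00117. Cdca7 rose by 1.40 ± 0.097, Ascl2 by 1.83 ± 0.16 and Igfbp4 by 1.81 ± 0.16 on the log2 scale. All 35 cell cycle genes rose (median 0.81; camera adjusted p = 1.01e-16, adjusted p = 0.151 with an estimated correlation, and permutation adjusted p = 0.00117) and all 30 ribosome biogenesis genes (median 1.06; camera adjusted p = 4.94e-19, adjusted p = 0.151 with an estimated correlation, and permutation adjusted p = 0.00219).

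Of 28 ERK output genes 16 rose, 2 fell and 10 did not pass, with 17 and 2 adjusted over the list alone. The ERK output list had a median log2 fold change of 0.41, camera adjusted p = 0.00323, adjusted p = 0.443 with an estimated correlation, and permutation adjusted p = 0.0219. In WT the libraries without Y-linked expression scored 4.51 to 4.61, within the ApcKras range, and the other 5 3.53 to 3.94. In ApcKras the 2 without it scored 4.74 and 5.197 and the other 4 4.36 to 4.57. The phosphatase gene Dusp4, a feedback inhibitor, changed by 1.82 ± 0.20, Spry1, an inhibitor of receptor signalling, by 0.76 ± 0.099 and Phlda1 by 1.72 ± 0.26. Of 23 glycolysis genes 17 rose, 2 fell and 4 did not pass, with 17 and 2 adjusted over the list alone. The glycolysis list had a median log2 fold change of 0.54, camera adjusted p = 1.68e-06, adjusted p = 0.119 with an estimated correlation, and permutation adjusted p = 0.00167. The carbonic anhydrase Car9 rose from 84.5 ± 8.97 to 203 ± 20.6 CPM, the glucose carrier Slc2a1 from 21.6 ± 3.90 to 56.5 ± 3.19 and the kinase Pgk1 from 115 ± 8.61 to 208 ± 25.8 (mean ± SD, n = 8 and 6). Of 23 amino acid transport and one-carbon genes 19 rose, 1 fell and 3 did not pass, with 20 and 2 adjusted over the list alone. The amino acid list had a median log2 fold change of 1.05, camera adjusted p = 3.19e-07, adjusted p = 0.151 with an estimated correlation, and permutation adjusted p = 0.00167. The serine hydroxymethyltransferase Shmt1 rose by 0.91 ± 0.097 and the carriers Slc1a4 and Slc38a1 by 1.996 ± 0.22 and 1.37 ± 0.17.

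Of 19 Paneth cell markers 0 rose, 15 fell and 4 did not pass, with 0 and 15 adjusted over the list alone. The Paneth cell list had a median log2 fold change of -1.52, camera adjusted p = 1.78e-05, adjusted p = 0.375 with an estimated correlation, and permutation adjusted p = 0.00848. Below all WT libraries in list score were 5 of the 6 ApcKras libraries, and without the exception, ApcKras replicate 1, the median was -2.35. Lysozyme, Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), fell from 3797 ± 1385 to 967 ± 1002 CPM (log2 fold change -1.97 ± 0.37, edgeR adjusted p = 4.47e-05). Without ApcKras replicate 1 the log2 fold change was -2.75 (edgeR adjusted p = 2.17e-08, in a range of 1.16e-08 to 0.00257 over 47 alternatives). The syntrophin Sntb1 changed by -1.39 ± 0.21 and the defensin Defa23 by -1.86 ± 0.41, though reads cannot be assigned with certainty among the near-identical defensin genes. Of 31 interferon response genes 0 rose, 29 fell and 2 did not pass, with 0 and 29 adjusted over the list alone. The interferon list had a median log2 fold change of -1.47, camera adjusted p = 6.78e-09, adjusted p = 0.348 with an estimated correlation, and permutation adjusted p = 0.00117. The GTPase genes Gbp4, Gbp2 and Iigp1 changed by -2.08 ± 0.24, -1.89 ± 0.33 and -1.99 ± 0.36. All 10 MHC class II genes fell (10 over the list alone; median -1.11; camera adjusted p = 0.00583, adjusted p = 0.443 with an estimated correlation, and permutation adjusted p = 0.00167), with H2-Eb1 from 345 ± 94.7 to 162 ± 71.6 CPM, H2-Ab1 at -1.17 ± 0.31 and H2-DMa at -1.03 ± 0.28, in a gene family whose alleles and copies share reads. The Y-expressing libraries alone gave 9 Paneth cell, 16 interferon and 4 class II genes lower (medians -1.32, -1.10 and -0.99).

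The largest rises with no overlap were in the water channel Aqp5 (7.04 ± 0.89; 6.29 without ApcKras replicate 4), Akp3 (6.04 ± 1.09; 4.92 without ApcKras replicate 6), the fatty acid carrier Slc27a6 (4.44 ± 0.33), the receptor Tnfrsf8 (4.01 ± 0.41), Cybrd1 (3.97 ± 0.59) and Msx1 (3.62 ± 0.35). Of the largest falls, Nt5e (-3.17 ± 0.37), an ectonucleotidase, and Prodh2 (-4.91 ± 0.91), a proline dehydrogenase, are single genes. The others belong to multigene families in which reads are assigned with uncertainty and some rest on few libraries. Defa31 was -7.996 ± 2.44 (edgeR adjusted p = 0.00653; -6.75 without WT replicate 6; -4.92 with limma voom, adjusted p = 0.161; -6.77 by edgeR in the Y-expressing libraries, adjusted p = 0.0747; in a range from 1.99e-06 over 47 alternatives), and the antibody gene segment Igkv2-112 was -6.49 ± 1.49 (-4.70 without WT replicate 1 and -7.75 without ApcKras replicate 6). The segment Ighv1-74 was -3.21 ± 0.69. H2-Ob was -3.46 ± 1.16, at edgeR adjusted p = 0.0126, and -1.77 without WT replicate 6, at adjusted p = 0.134. H2-Ob was -1.58 in the Y-expressing libraries alone (edgeR adjusted p = 0.347, in a range from 1.53e-07 over 47 alternatives).

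Of 30 brush border genes 1 rose, 9 fell and 20 did not pass, with 1 and 7 adjusted over the list alone. The list had camera adjusted p = 0.0129, adjusted p = 0.524 with an estimated correlation, and permutation adjusted p = 0.0219. Of 25 lipid absorption genes 1 rose, 13 fell and 11 did not pass, with 1 and 13 adjusted over the list alone. That list had camera adjusted p = 0.0147, adjusted p = 0.489 with an estimated correlation, and permutation adjusted p = 0.00833. Of 30 xenobiotic genes 0 rose, 14 fell and 16 did not pass, with 0 and 14 adjusted over the list alone, at camera adjusted p = 0.00135, adjusted p = 0.489 with an estimated correlation, and permutation adjusted p = 0.00219. Without ApcKras replicate 4 camera gave adjusted p = 0.106 for brush border and 0.0595 for lipid genes, each in a range from 0.00449 over 38 alternatives. The Y-expressing libraries gave 4 brush border, 3 lipid absorption and 7 xenobiotic genes lower. Goblet (15 of 19 lower), enteroendocrine (15 of 23), tuft (11 of 16), T cell (19 of 20), fibroblast (17 of 18), endothelial (13 of 16) and enteric neuron and glia (14 of 19) lists were lower by camera, at adjusted p = 0.119 to 0.397 with an estimated correlation. In the Y-expressing libraries 14 goblet, 14 enteroendocrine, 8 tuft, 17 T cell, 14 fibroblast, 12 endothelial and 9 enteric neuron and glia genes were lower.

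Of the genes changed against WT, 4354 were higher and 3552 lower in both Apc and ApcKras, where independent lists would share 1668 and 1430. In 20 simulations with unchanged groups the highest shared count was 0 in each direction. That is chance with no effect, and it does not show what the shared WT samples add where many genes change. With the WT samples split in 2 sets of 4, so that each comparison had its own controls, 3333 and 3491 genes were higher in both (independent lists, 1151 and 1156) and 2253 and 2628 lower (909 and 924).

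**Figure D3:**
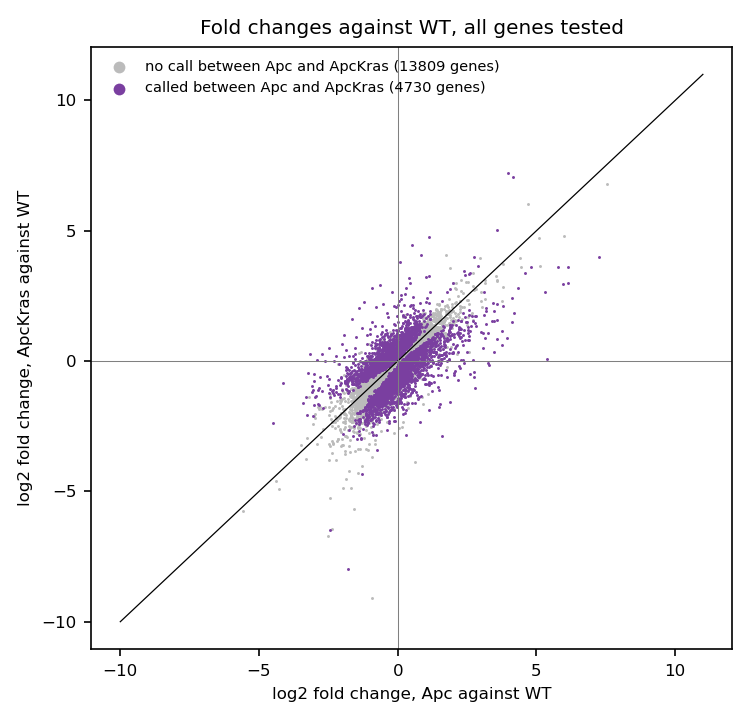
Each point is 1 of 18539 genes, with its log2 fold change in Apc against WT on the horizontal axis and in ApcKras against WT on the vertical axis. Most points lie along the diagonal of equal change, and the 4730 genes called between ApcKras and Apc, in purple, lie off it to both sides.

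The comparison of ApcKras with Apc asks what KRasG12D adds to loss of Apc, and day 3 against day 4 differs along with genotype. Of 24 Wnt targets 14 were lower in ApcKras, and of 17 stem cell markers 8, the latter at adjusted p = 0.105 with an estimated correlation. Of 35 cell cycle and 30 ribosome biogenesis genes 1 and 2 were called. Of 23 glycolysis genes 17 were higher. Of the 25 members of the lipid absorption list and the 23 of the amino acid list 17 and 12 were higher, these 2 lists at adjusted p = 0.311 and 0.369 with an estimated correlation. Of 26 BMP pathway genes 12 were lower. Of 19 Paneth cell, 31 interferon and 10 class II genes 9, 26 and 7 were lower, at adjusted p = 0.346, 0.369 and 0.462 with an estimated correlation. Of 18539 genes, 2565 were higher and 2165 lower (297 and 507 by at least 2-fold; edgeR quasi-likelihood, Benjamini-Hochberg). Of the called genes 54.2% were higher, and 36.5% with upper-quartile factors (median log2 fold change of all genes -0.074). Among 3330 called genes with at least 5 CPM and a symbol not passed over, 175 higher and 129 lower genes had no overlap. Camera called 16 lists (6 up, 10 down), of which 3 held with an estimated correlation, and the exact permutation test called 13 (3 up, 10 down), 12 of them among the 16. In 6 lists that camera did not call, cell cycle genes among them (median -0.030, mean 0.013), the median, mean and camera direction differ in sign.

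Of 24 Wnt targets 1 rose, 14 fell and 9 did not pass, with 1 and 14 adjusted over the list alone. The Wnt target list had a median log2 fold change of -0.59, camera adjusted p = 2.00e-13, adjusted p = 0.00780 with an estimated correlation, and permutation adjusted p = 9.88e-05. In list score 6 of 6 ApcKras libraries lay below all 19 Apc libraries. The lymphatic and secretory transcription factor Prox1 fell from 21.9 ± 9.84 to 2.53 ± 0.435 CPM (mean ± SD, n = 19 and 6; log2 fold change -3.11 ± 0.27, edgeR adjusted p = 7.83e-10), the feedback inhibitor Nkd1 from 73.4 ± 20.7 to 14.9 ± 3.18 (-2.30 ± 0.18) and the receptor Tnfrsf19 from 82.7 ± 25.2 to 22.5 ± 2.92 (-1.88 ± 0.19). Nkd1 was at 14.4 ± 3.10 CPM in WT (n = 8). Of 17 stem cell markers 0 rose, 8 fell and 9 did not pass, with 0 and 13 adjusted over the list alone. The stem cell list had a median log2 fold change of -0.38, camera adjusted p = 3.84e-08, adjusted p = 0.105 with an estimated correlation, and permutation adjusted p = 0.000198, and 14 fell in the Y-expressing libraries. The urea carrier Slc14a1 changed by -2.44 ± 0.25, the BMP co-receptor Rgmb by -0.85 ± 0.10 and the R-spondin receptor Lgr5 by -1.32 ± 0.21, from 55.3 ± 13.8 to 22.0 ± 8.29 CPM. Of 35 cell cycle genes 1 rose, 0 fell and 34 did not pass, with 0 and 0 adjusted over the list alone, and of 30 ribosome biogenesis genes 2 rose, 0 fell and 28 did not pass, with 0 and 0 adjusted over the list alone. The Y-expressing libraries gave a cell cycle median of -0.16 with 2 genes lower, and camera called that list lower there (adjusted p = 0.0254, against 0.953 in all libraries).

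**Figure D4:**
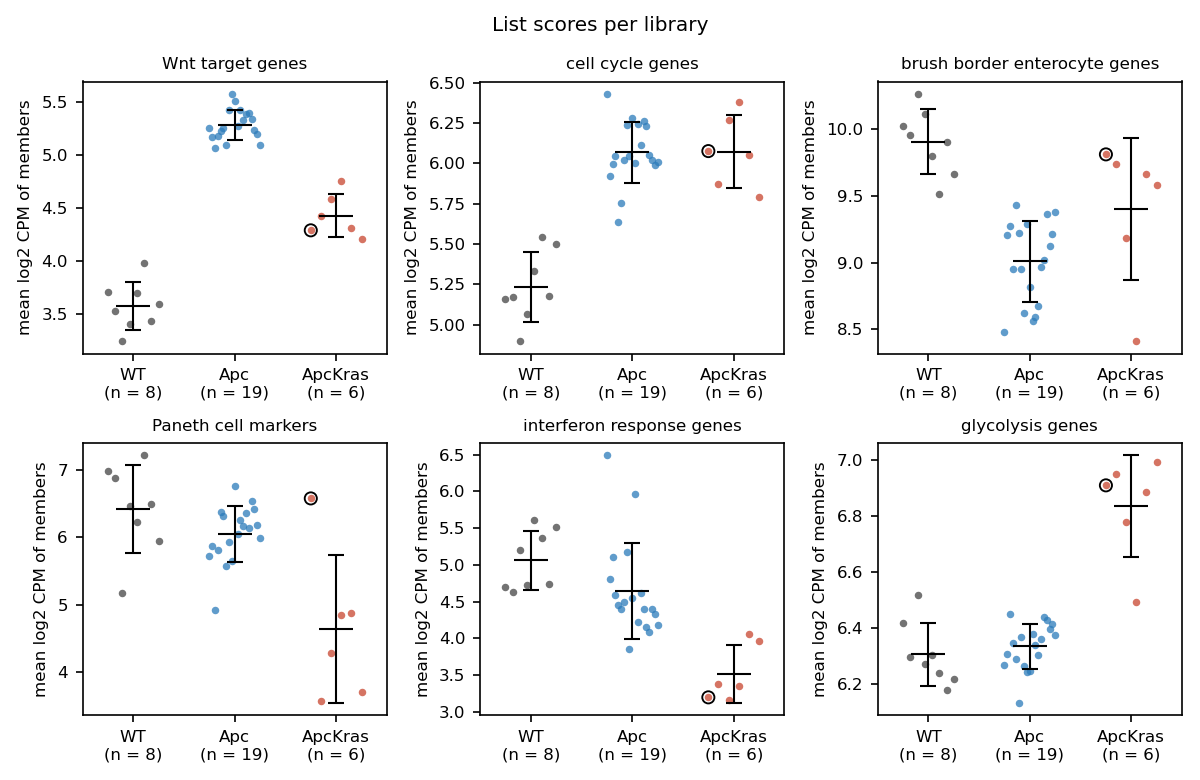
List scores, the mean log2 CPM over the members of a list, for 6 lists, with 1 point per library, bars at the mean ± SD and a circle around ApcKras replicate 1. The Wnt target scores of all 6 ApcKras libraries lie above WT and below Apc, and the glycolysis scores of all 6 lie above Apc.

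Of 26 BMP and TGF-beta pathway genes 1 rose, 12 fell and 13 did not pass, with 1 and 14 adjusted over the list alone. The BMP list had a median log2 fold change of -0.43, camera adjusted p = 2.77e-06, adjusted p = 0.00421 with an estimated correlation, and permutation adjusted p = 0.000751. Msx1 changed by -2.53 ± 0.28, the ligand Bmp4 by -0.78 ± 0.11 and the target Id2 by -0.69 ± 0.094. Of 19 Notch pathway genes 2 rose, 9 fell and 8 did not pass, with 3 and 10 adjusted over the list alone (camera adjusted p = 0.00725, adjusted p = 0.309 with an estimated correlation). Of 19 Paneth cell markers 0 rose, 9 fell and 10 did not pass, with 0 and 11 adjusted over the list alone. The Paneth cell list had a median log2 fold change of -1.01, camera adjusted p = 1.14e-08, adjusted p = 0.346 with an estimated correlation, and permutation adjusted p = 0.00224. Of the 6 ApcKras libraries 5 scored below all Apc libraries, and without ApcKras replicate 1, 17 members fell, with a median of -1.77. The phospholipase Pla2g2f, the ligand Wnt3 and Habp2, a serine protease, changed by -1.55 ± 0.23, -1.39 ± 0.23 and -1.64 ± 0.30.

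Of 31 interferon response genes 0 rose, 26 fell and 5 did not pass, with 0 and 30 adjusted over the list alone. The interferon list had a median log2 fold change of -1.24, camera adjusted p = 1.12e-10, adjusted p = 0.369 with an estimated correlation, and permutation adjusted p = 0.00268. The RNA-binding antiviral genes Ifit1bl1, Ifit1 and Ifit2 changed by -2.26 ± 0.42, -2.02 ± 0.40 and -2.12 ± 0.42, and Ifit1 had 94.8 ± 42.1 CPM in WT, 87.2 ± 65.1 in Apc and 21.5 ± 5.70 in ApcKras (n = 8, 19 and 6). Of 10 MHC class II genes 0 rose, 7 fell and 3 did not pass, with 0 and 7 adjusted over the list alone. The class II list had a median log2 fold change of -1.02, camera adjusted p = 0.00177, adjusted p = 0.462 with an estimated correlation, and permutation adjusted p = 0.0114. H2-Ab1 changed by -0.996 ± 0.28, H2-DMb1 by -1.08 ± 0.31 and the class II transactivator Ciita by -1.04 ± 0.30. In the median of 20 draws of 6 samples per group their log2 fold changes were as large (-1.07, -1.14 and -1.03), but none passed (edgeR adjusted p = 0.0552, 0.0606 and 0.0564). In the Y-expressing libraries they were -0.70, -0.79 and -0.81 and did not pass either (0.0972, 0.118 and 0.0837, the highest of 47 alternatives each). Without ApcKras replicate 1, 4 of the 10 list members fell. Class II scores were 4.67 to 6.51 in Apc replicates 1 to 11, 4.49 to 5.09 in replicates 12 to 19 and 3.87 to 5.22 in ApcKras. How much of the fall rests on the first of these Apc sets, divided on component 4, was not tested. The Y-expressing libraries gave 10 of 31 interferon (median -0.90) and 0 of 10 class II genes lower (median -0.75).

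Of 23 glycolysis genes 17 rose, 0 fell and 6 did not pass, with 18 and 0 adjusted over the list alone. The glycolysis list had a median log2 fold change of 0.66, camera adjusted p = 1.93e-15, adjusted p = 0.00421 with an estimated correlation, and permutation adjusted p = 9.88e-05. All 6 of 6 ApcKras libraries scored above all Apc libraries. Car9 rose from 119 ± 13.0 to 203 ± 20.6 CPM (log2 fold change 0.77 ± 0.072, edgeR adjusted p = 2.03e-09), Slc2a1 from 27.6 ± 4.83 to 56.5 ± 3.19 (1.03 ± 0.10) and Pgk1 from 130.4 ± 13.3 to 208 ± 25.8 (0.67 ± 0.069). Of 23 amino acid transport and one-carbon genes 12 rose, 0 fell and 11 did not pass, with 14 and 0 adjusted over the list alone. The amino acid list had a median log2 fold change of 0.43, camera adjusted p = 7.72e-05, adjusted p = 0.369 with an estimated correlation, and permutation adjusted p = 0.00321. The call was lost in the Y-expressing libraries (camera adjusted p = 0.290, 3 of 23 higher, in a range from 3.06e-06 over 38 alternatives), and ApcKras replicates 3 and 4 scored 6.37 to 6.42 and the other 4 ApcKras libraries 5.50 to 5.68. The stress-response genes Trib3 and Chac1 changed by 1.45 ± 0.15 and 1.92 ± 0.33 (Chac1 in the Y-expressing libraries 1.08, edgeR adjusted p = 0.0506, in a range from 1.61e-06) and the taurine carrier Slc6a6 by 0.67 ± 0.11. Of 28 ERK output genes 9 rose, 3 fell and 16 did not pass, with 9 and 3 adjusted over the list alone. The ERK output list had a median log2 fold change of 0.19, camera adjusted p = 0.0575, adjusted p = 0.792 with an estimated correlation, and permutation adjusted p = 0.534, and was not called in this comparison. The ERK phosphatase gene Dusp5 (ENSMUSG00000034765, chromosome 19, 53529109 to 53542431) was at 31.9 ± 3.28 CPM in WT, 16.2 ± 3.19 in Apc and 32.7 ± 5.32 in ApcKras (n = 8, 19 and 6; ApcKras against Apc 1.01 ± 0.10, edgeR adjusted p = 1.05e-08). Emp1, a membrane protein, changed by 0.70 ± 0.11 and the metalloproteinase Mmp10 by -1.03 ± 0.13.

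Of 25 lipid absorption genes 17 rose, 0 fell and 8 did not pass, with 17 and 0 adjusted over the list alone. The lipid absorption list had a median log2 fold change of 0.52, camera adjusted p = 2.37e-07, adjusted p = 0.311 with an estimated correlation, and permutation adjusted p = 0.00843. Without ApcKras replicate 1, 11 of these 25 genes rose, and in the Y-expressing libraries 20. Mttp changed by 0.90 ± 0.12, the mitochondrial fatty acid importer Cpt1a by 0.65 ± 0.10 and Gpd1, which makes glycerol phosphate, by 0.52 ± 0.086. Of 30 xenobiotic genes 15 rose, 0 fell and 15 did not pass, with 17 and 0 adjusted over the list alone. The xenobiotic list had a median log2 fold change of 0.64, camera adjusted p = 2.15e-07, adjusted p = 0.419 with an estimated correlation, and permutation adjusted p = 0.0640. In the Y-expressing libraries 20 rose (median 0.87). ApcKras replicates 3 and 4 scored 4.62 to 5.82 and the other 4 ApcKras libraries 6.54 to 7.16. Gsta1 changed by 2.98 ± 0.37, Gsta4 by 2.39 ± 0.21 and the carboxylesterase Ces2c by 1.36 ± 0.20. Of 30 brush border genes 12 rose, 0 fell and 18 did not pass, with 14 and 0 adjusted over the list alone. The brush border list had a median log2 fold change of 0.47, camera adjusted p = 3.98e-05, adjusted p = 0.544 with an estimated correlation, and permutation adjusted p = 0.0768, and 18 rose in the Y-expressing libraries. Camera also called oxidative phosphorylation genes higher (6 of 28 rose) and T cell markers lower (2 of 20 fell), each at adjusted p = 0.828 with an estimated correlation and at permutation adjusted p = 0.180 and 0.292. The Y-expressing libraries gave 18 oxidative phosphorylation genes higher, but the call was lost with a replicate block (camera adjusted p = 0.628), in the libraries under 21000000 counts (0.137) and without ApcKras replicate 1 (0.194, with 2 genes higher), in a range of 4.10e-07 to 0.628 over 38 alternatives. The T cell call was lost without Apc replicate 1, 2, 7, 8, 9, 10 or 11 (0.0509 to 0.0609) and without ApcKras replicate 1, 3 or 4 (0.0731 to 0.278), and in the Y-expressing libraries (0.630), in a range from 6.26e-05. T cell scores were 2.03 to 2.94 in Apc replicates 1 to 11, 1.35 to 2.11 in replicates 12 to 19 and 1.23 to 2.60 in ApcKras. The fall thus lay mainly against the first of the Apc sets that component 4 divides. Fibroblast (9 of 18) and endothelial (9 of 16) markers fell by camera, at adjusted p = 0.369 and 0.427 with an estimated correlation. The endothelial call was lost in the Y-expressing libraries (camera adjusted p = 0.0558, in a range from 5.54e-05 over 38 alternatives).

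The largest rise with no overlap was in Slc27a6 (ENSMUSG00000024600, chromosome 18, 58556257 to 58612773), from 0.957 ± 0.417 to 14.8 ± 3.70 CPM (log2 fold change 3.92 ± 0.23, edgeR adjusted p = 5.67e-14). Next came the transcription factor Tcf23 (3.58 ± 0.22), Gsta4, the methylarginine hydrolase Ddah1 (2.25 ± 0.30), the glucose-6-phosphatase G6pc (2.12 ± 0.38) and Gprc5a (2.04 ± 0.25), an orphan receptor. The largest fall was in the endoderm factor Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), from 15.6 ± 9.20 to 1.12 ± 0.422 CPM (-3.82 ± 0.40). It was followed by Prox1, the muscle protein gene Neb (-3.09 ± 0.38), Notum (-2.65 ± 0.32), Msx1 and the matrix protein gene Dmp1 (-2.45 ± 0.23).

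**Figure D5:**
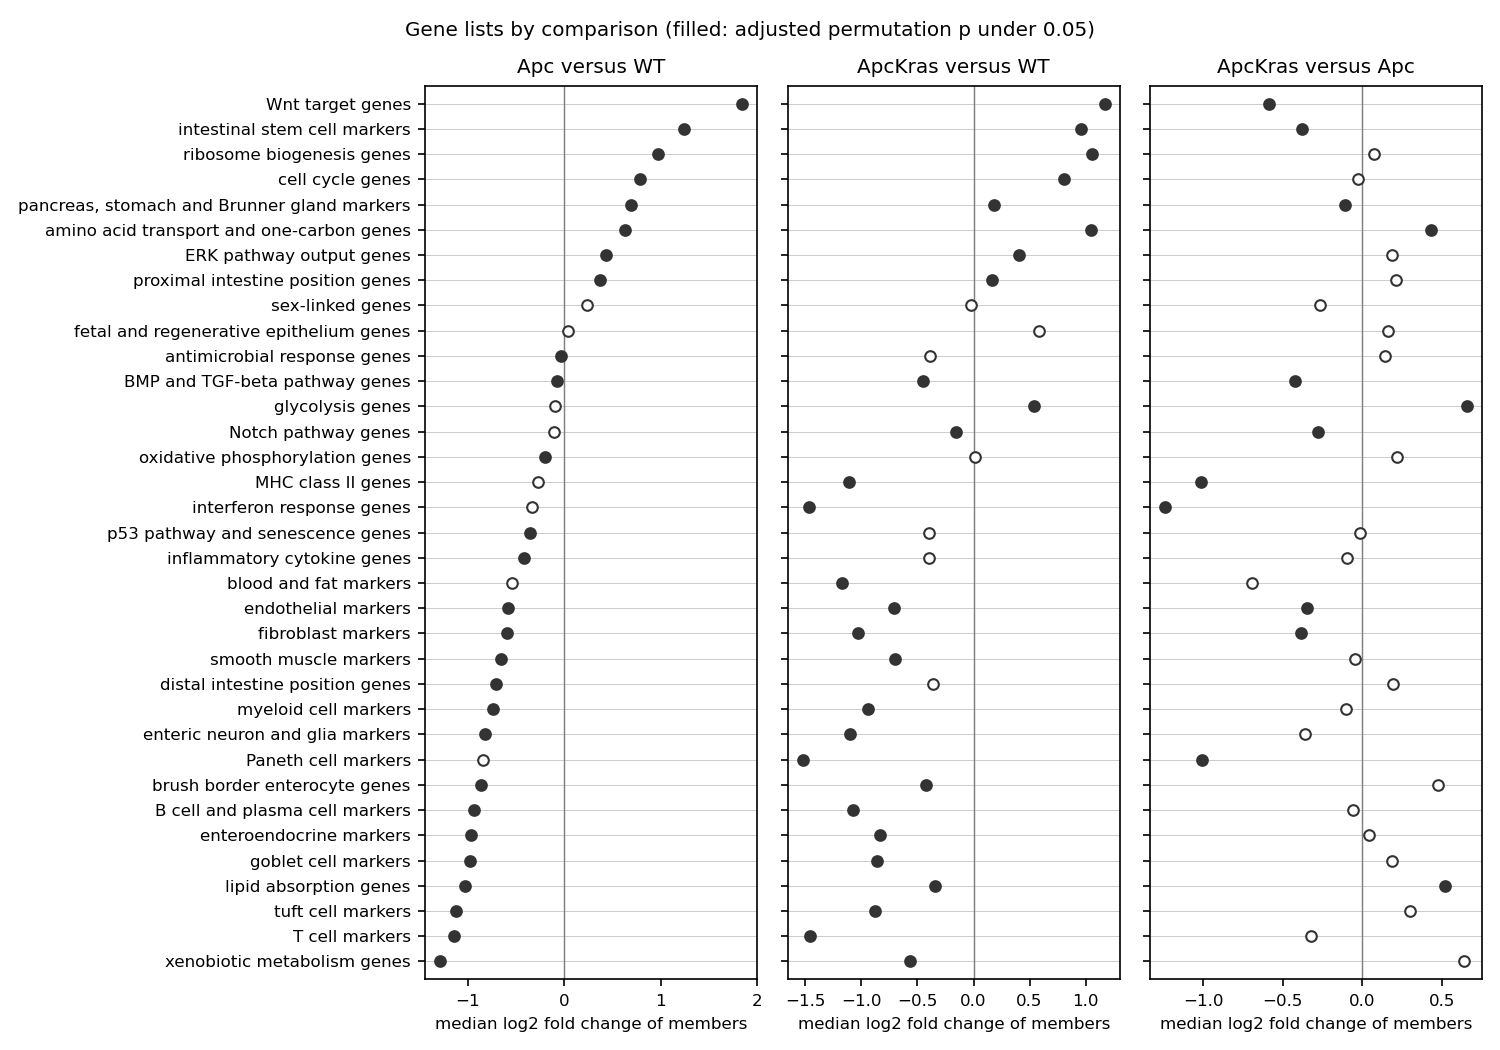
Median log2 fold change of the measured members of each of 35 gene lists in the 3 comparisons, with filled points where the permutation adjusted p of the list score was under 0.05. Wnt targets lie to the right in both comparisons with WT (medians 1.84 and 1.17) and to the left in ApcKras against Apc (-0.59).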

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

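The tests of a wrong label, of a more distal sample, of fewer recombined cells and of a few high Apc libraries were chosen only after the results were seen. Library totals, 121 named genes and 35 list scores were searched for single samples far from the others of their group by Dixon's gap test, in 314 groups of the WT (n = 8) or ApcKras (n = 6) samples. For independent, normally distributed values chance picks out about 1 in 20 groups, here about 15.7. In all, 32 were picked out, 10 of them in ApcKras replicate 1 and 8 in ApcKras replicate 6. The CPM were not log-transformed and many of the genes vary together, so the number by chance is not known here. The Apc group of 19 samples was not searched.

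ApcKras replicate 1 stood above the other ApcKras samples in Lyz1 (2988 CPM against 334 to 769), Wnt3 (10.2 against 3.05 to 5.26), Habp2 (18.5 against 2.70 to 6.63), Defa23 (25.3 against 6.07 to 9.79) and Sntb1 (3.69 against 1.72 to 2.20), which are Paneth cell markers. It was also highest in Dnase1 (338 against 9.80 to 99.1), Slc34a2 (115 against 3.58 to 30.0), Dusp5 (43.4 against 29.3 to 31.7) and the distal intestine score (5.63 against 3.88 to 4.48), and lowest in Ifit2 (3.19 against 6.74 to 8.47).

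ApcKras replicate 6 was highest in Akp3 (964 CPM against 7.30 to 275), Gja1 (29.9 against 18.2 to 20.5), H2-Ob (2.27 against 0.538 to 1.14), Igkv2-112 (0.567 against 0 to 0.168), S100a8 (10.4 against 0.117 to 0.419) and S100a9 (15.1 against 0.165 to 1.85). Its scores were also highest for myeloid cell markers (4.24 against 2.42 to 2.85) and inflammatory cytokine genes (2.53 against 0.77 to 1.33). ApcKras replicate 4 was lowest in Apoa4 (1560.3 CPM against 3120.4 to 4013) and had the highest score of p53 pathway and senescence genes (5.85 against 5.07 to 5.15). ApcKras replicate 2 had the lowest score of enteric neuron and glia markers (-0.70 against 1.02 to 1.85).

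Among the WT samples, replicate 6 was highest in H2-Ob (67.3 CPM against 2.36 to 4.62), Defa31 (239 against 0.514 to 109.8), the score of B cell and plasma cell markers (7.26 against 4.95 to 5.90) and that of MHC class II genes (7.001 against 4.99 to 5.91). Replicate 1 was highest in Ighv1-74 (57.9 CPM against 4.05 to 27.1) and Igkv2-112 (75.2 against 0.57 to 9.89). Replicate 2 was lowest in Cd14 (5.17 CPM against 9.44 to 12.1) and in the smooth muscle score (5.54 against 6.50 to 7.01) and highest in Gkn3 (7.64 against 1.23 to 3.60). Replicate 3 was highest in Aldob (4790.5 CPM against 3051 to 3752) and replicate 8 in Iigp1 (35.97 against 18.4 to 25.1).

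The Paneth cell score of ApcKras replicate 1 was 6.58, within the ranges of the WT (5.17 to 7.22) and the Apc samples (4.93 to 6.77). It lay above the other ApcKras samples (3.57 to 4.88). A wrong group label is argued against by its Wnt target score of 4.29, near the other ApcKras samples (4.21 to 4.75), above all WT samples (highest 3.98) and below all Apc samples (lowest 5.06). A sample taken from farther along the intestine may account for it and stays open: 2 of 9 distal genes were highest in this library of all 33, no more than the 2 allowed for by the test, but chance gives 0.273. By that limit alone the explanation would be excluded. It was left open only after the count was seen, since all 9 genes ranked at least 7 of 33 in this library and its distal score of 5.63 exceeded every other (highest 4.78). The distal gene Fabp6 was at 7.72 CPM in this library, against at most 0.759 in the other ApcKras, 0.999 in the Apc and 0.698 in the WT samples. The proximal score of this library, 5.24, lay below the other ApcKras (5.94 to 7.07) and all Apc samples (5.57 to 6.99). It lay within the WT samples (5.21 to 5.43). No biological explanation was tested, because the labels name no difference within the group.

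The Wnt targets were lower in ApcKras than in Apc. Fewer recombined cells would dilute every induced gene alike. The 35 cell cycle genes kept a median of 95.7% of their rise over WT, and the 20 Wnt targets that rose in Apc kept 53.4%. The difference was 42.3 ± 13.4 (SE of a bootstrap over genes, which does not measure the spread between libraries). The 30 ribosome biogenesis genes kept 111%, and in the libraries with Y-linked expression alone the 3 shares were 80.7%, 45.6% and 91.4%, with a difference of 35.05 ± 10.5 between the first 2. Across genes, dilution is thus argued against as the whole explanation. The spread of these shares between libraries was not tested, nor was dilution together with a separate rise of the growth genes. KRasG12D and the harvest 1 day earlier cannot be told apart, since 0 ApcKras libraries were taken on the day of the Apc libraries.

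The interferon response genes were lower in ApcKras than in Apc, with a median log2 fold change of -1.24 and 26 of 31 genes called (camera adjusted p = 1.12e-10, adjusted p = 0.369 with an estimated correlation). Fewer T or myeloid cells are argued against, as far as their scores measure them: with both scores as covariates the median was -1.18, and 24 of 26 genes were still lower. Mean T cell scores were 2.20 in Apc and 1.88 in ApcKras, and myeloid scores 2.94 and 2.96, so the adjustment had little to remove. ApcKras replicate 6 (4.24) raised the last mean, the other ApcKras libraries being at 2.42 to 2.85. Other immune cells were not covered. A few Apc libraries with high values are argued against too, since the ratio of group medians gave -1.17 and 18 of 19 Apc libraries scored above all ApcKras libraries. For the libraries with Y-linked expression alone the median was -0.90, and 10 genes were lower. KRasG12D and the harvest 1 day earlier cannot be told apart for this list either, with 0 ApcKras libraries on the later day.

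The counts of genes were set against 100 random regroupings of the libraries, the real one included. In Apc against WT the real grouping gave 5806 higher and 5795 lower genes, and the highest of the others 148 and 363. In ApcKras against WT it gave 5326 and 4574, against 2449 and 3727, and in ApcKras against Apc 2565 and 2165, against 982 and 631. Of genes changed in the same direction against WT in both groups it gave 4354 higher and 3552 lower, against 0 and 0. In each of these 8 counts only 1 of the 100 groupings, the real one, reached that number. Chance is thus argued against, but 100 groupings cannot exclude it. For the counts shared by both groups, all libraries were regrouped, which tests only the absence of any difference. For the number of lists that camera called, chance is not argued against. As many as the real 17 in Apc against WT came from 31 of 100 groupings (highest other 25). In ApcKras against WT 18 gave as many as 23 (28), and in ApcKras against Apc 37 as many as 16 (21).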

How the results depend on the processing

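The exact permutation test of lists, the counts of list members without ApcKras replicate 1 and the restrictions to libraries under 21000000 counts and to libraries with Y-linked expression were chosen only after the results were seen. In Apc against WT and ApcKras against WT, the counts of higher and lower genes stayed within 1.5 times the reported ones under every alternative run on all genes but 1. The libraries with Y-linked expression gave 3012 lower genes in ApcKras against WT (2848 of the reported 4574) and 2238 genes lower in both groups against WT (reported 3552). Whether the smaller number of libraries or what sets them apart decides this was not tested. With each of the 33 libraries left out in turn all 6 counts of genes, both counts shared against WT and all 3 counts of lists stayed within 1.5 times. Drawing 6 samples per group gave median totals of 8271 changed genes in Apc against WT and 8527.5 in ApcKras against WT, so at equal numbers of samples the count was no longer higher in Apc against WT.

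The comparison of ApcKras with Apc depended more on the processing. Higher genes numbered 1515 with no low-count filter, of which 1335 were among the reported 2565, 1197 with a replicate block (977 shared) and 1029 with 6 samples drawn per group. Lower genes numbered 1017 with a replicate block (924 of the reported 2165) and 1128.5 with 6 samples drawn per group. Fewer samples explain the counts with 6 drawn. In the replicate block Apc replicates 9 to 19 each have a level of their own, so they do not bear on its fold changes. The block also spends degrees of freedom on numbers that do not pair the samples. For the filter the cause was not tested.

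Lists depended on the test. With an estimated correlation camera called 2 lists in Apc against WT, 0 in ApcKras against WT and 3 in ApcKras against Apc, since the estimated correlation between members widens the test. The exact permutation of list scores called 27 in Apc against WT (reported 17). It tests a list by itself, not against other genes. The rotation test fry called 24, 30 and 14 of 35 lists in the order of the comparisons above. Without ApcKras replicate 1, 16 of 19 Paneth cell markers were lower in ApcKras than in WT and 17 than in Apc. The RLE factors, the filter of 1 CPM, the replicate block, the shallower libraries and those with Y-linked expression left all 3 counts of lists within 1.5 times.

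For the 145 results of named genes, 6795 values were obtained under alternatives. Of these, 6756 kept their side of the threshold, 34 lost the call, 4 gained it and 1 reversed. A value called neither in the main fit nor under the alternative counted as kept, whatever its direction. The changes fell on 14 results. The reversal was S100a8 in ApcKras against Apc, at a log2 fold change of -0.028 without ApcKras replicate 6, with up to 3.14 when other libraries were left out, and under the alternatives in which it was tested, limma voom among them, its adjusted p ran from 0.000177 to 0.975. Apc in both comparisons with WT, Kras in 2 comparisons, Defa31, H2-Ob, S100a6, H2-Ab1, H2-DMb1, Ciita, Chac1, S100a9 and Cd14 each lost or gained a call under at least 1 alternative, and the cause was not tested except where a single library decided. In the simulations edgeR recovered 46.3% to 55.2% of changes of 1.5-fold, so small changes can be missed.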

Other observations

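The lists described here were named after the results were seen, by the rule for named genes. In Apc against WT, 4 of 8 measured markers of pancreas, stomach and Brunner glands were higher and 2 lower (permutation adjusted p = 2.43e-06, camera adjusted p = 0.205, and 0.373 with an estimated correlation). The gastric genes Gkn3 and Pgc were at 25.5 ± 11.2 and 6.12 ± 1.83 CPM in Apc and 2.83 ± 2.13 and 0.866 ± 0.510 in WT (mean ± SD, n = 19 and 8), and the pancreatic gene Cpb1 was at 0.284 ± 0.151 and 0.714 ± 0.222. Of 9 genes of the proximal intestine 3 were higher and 4 lower (permutation adjusted p = 0.000109, camera adjusted p = 0.831). The score was 0.69 higher in Apc and 19 of 19 Apc libraries lay above all WT libraries, with the iron exporter Slc40a1 at log2 fold change 3.58 ± 0.34, Cybrd1 at 4.40 ± 0.55 and the alcohol dehydrogenase Adh1 at -1.93 ± 0.24. Of 9 genes of the distal intestine 1 was higher and 5 lower (permutation adjusted p = 1.38e-05, camera adjusted p = 0.0537), and 17 of 19 Apc libraries scored below all WT libraries. Of 18 antimicrobial response genes 1 was higher and 7 lower, among them Ido1 (-1.96 ± 0.20), Lypd8 (-1.16 ± 0.17) and Reg3a (-2.97 ± 0.48).

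The Paneth cell markers went both ways in Apc against WT: of 19, 3 rose, 9 fell and 7 did not pass (permutation adjusted p = 0.106). Pla2g2f (1.74 ± 0.20) and Wnt3 (1.20 ± 0.20) were higher and Sntb1 (-0.91 ± 0.15) lower.

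In ApcKras against Apc the myeloid list was not called (camera adjusted p = 0.665), and its median (-0.10) and mean (0.29) differ in sign. Its members S100a9 (3.49 ± 0.58) and S100a8 (2.88 ± 0.59) rest on ApcKras replicate 6: without it S100a9 was at 1.19 (edgeR adjusted p = 0.106, in a range from 1.82e-06, with 0.103 by limma voom) and S100a8 at -0.028 (0.975, in a range from 0.000177). Cd14 was at 0.75 ± 0.17, and did not pass with 6 samples drawn per group (edgeR adjusted p = 0.0755, in a range from 0.000412). Of 22 fetal and regenerative epithelium genes 4 were higher and 2 lower (camera adjusted p = 0.574), with Ccn2 at 8.87 ± 2.76, 15.4 ± 3.93 and 41.6 ± 13.1 CPM in WT, Apc and ApcKras (n = 8, 19 and 6), S100a6 at 1.21 ± 0.27 (not passed with a replicate block, edgeR adjusted p = 0.0575, in a range from 8.78e-05 over 47 alternatives) and Gja1 at -0.82 ± 0.14.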
